A study of Sinocyclocheilus angustiporus and Sinocyclocheilus anophthalmus with 4 samples.

How the data were processed

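The series holds 4 libraries, 1 each of eye and brain of a surface fish and a cavefish; the 2 eye libraries were compared and the brain libraries were not analysed here. Per the labels' protocols, total RNA was extracted from whole eyes of adult fish with TRIzol, polyadenylated RNA was selected with oligo(dT), and paired-end libraries were sequenced on an Illumina Genome Analyzer or HiSeq instrument. Which library ran on which instrument is not stated, so a difference of platform and of species cannot be told apart. The labels name 2 individuals per species and do not say how they enter a library.

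Per the file headers, the deposited values are RPKM, computed by the authors for 9649 rows in each of 2 tables, 1 per eye, with the same row names in the same order. RPKM divides the reads of a transcript by its length and by the number of mapped reads, so that values of different genes share a scale, and a few very abundant transcripts lower all others. Bowtie 0.12.2 is named in the submitters' processing notes, with no role stated. The reference or assembly to which reads were aligned, the transcript lengths, and the treatment of reads that match several genes are not given in the sources used here. Each table's column was assigned to its library through the fish named in its header and the matching sample title. No row of the tables was at 0, and none had both values under 5 RPKM: the larger value of a row was 5 at least. The tables thus leave out genes low in both eyes. Whole reads could not be recovered, since this takes genes with few reads in both libraries; the depth is unknown and no counting error was computed.

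Names occurred on more than 1 row for 64 of 9585 different names. List symbols were matched through 655 descriptive names, from the names alone and before any ratio was computed, which joined further rows of a gene; the 9 names of a liver list were added after ratios had been seen. Of a gene with several rows the row with the largest sum over both eyes was used, which left 9521 genes. For each gene, log2((cavefish RPKM + 1) / (surface fish RPKM + 1)) was computed on the deposited scale; it understates the change of genes with low values. Genes with a larger value of 1 or more were kept, which removed none. A log2 ratio of 1 or -1 was the threshold of 2-fold. No test was made, since each group had 1 library.

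Before the data were examined, 26 gene lists of zebrafish symbols were fixed for tissues and pathways of an eye and for other tissues that a dissected eye can hold. For each list the median log2 ratio of its measured members was placed among medians of 10000 random lists of the same size, drawn with a fixed seed from the same 20 bins of mean expression. The percentile describes these libraries and is not a test. A median below the 2.5th or above the 97.5th percentile was said to stand apart. A list of mitochondrially encoded transcripts was added from row names after the tables were opened, before ratios were computed, and a list of liver transcripts after the largest ratios had been seen. The number of lists standing apart, as a summary of the list medians, was also chosen after the medians had been seen.

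The genes named were set by a rule written in advance: the 12 largest and 12 smallest log2 ratios among genes reaching 10 RPKM, the 10 most abundant genes of each library, the 4 members past 2-fold with the largest higher value in each list that stood apart or had 5 or more members past 2-fold, and 19 eye and control genes, of which opn1sw1 and cryaa were not matched. Other genes were named after their values were seen: sox2, lhx2b, abca4a, glulb, cahz, mipb, bfsp2, krt8, krt18, cdh1, hsp90aa1.2, per1b and per3 in the report, and the genes of the closing observations.

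The computation was tested on simulated values for the same genes, with an assumed noise of 0.3 (SD, log2). This noise was not estimated, since each group had 1 library. The shares below follow from it and give no rate of false calls in the real libraries. Of 100 genes changed 3-fold, 95% passed 2-fold in the right direction, as did 100% of 100 genes changed 8-fold, and 0.0215% of 9293 unchanged genes passed. A list shifted by -1 gave a median of -0.99 and lay below all its random lists, while 2 of 25 lists without a shift lay outside the central 95%. Alternatives were pseudocounts of 0.1 and 5, other filters, 4 other scalings (centring on the median, a trimmed mean of log2 ratios, equal totals without the 50 most abundant genes of either library, and quantile normalization), a threshold of 4-fold, rows summed per gene, other random lists, and lists without shared members. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.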

Results

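Gene expression was measured by RNA sequencing in whole eyes of adult fish of 2 Sinocyclocheilus species, freshwater fish of the carp family from China. Sinocyclocheilus angustiporus lives at the surface, and Sinocyclocheilus anophthalmus is a cavefish that lives in the dark. The series also labels a brain library of each species; the brain libraries were not analysed here. Each eye was represented by 1 library, so no difference below has a replicate check, and no p-value or error between animals can be given. The labels name 2 individuals per species, without saying whether their RNA was pooled. Values were RPKM, reads scaled to transcript length and to the number of mapped reads, as the authors deposited them. They summed to 684735.55 in the surface fish eye and 665573.62 in the cavefish eye. The number of reads behind a value is not known, so no counting interval is given. Rows carried descriptive gene names; the symbols used here are those of zebrafish genes matched by name, and a paralog letter is only as sure as that match.

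The comparison asked how the eye transcriptome of a cave species differs from that of a surface relative. Genes of rod and cone phototransduction were lower in the cavefish eye, as were the lists of cornea and skin epithelium, erythrocytes and nuclear-encoded oxidative phosphorylation, by their medians. Lens crystallins, skeletal muscle genes, chaperones, cytosolic ribosomal protein genes and the measured Wnt pathway genes lay above genes of like abundance. For the Wnt list, 26 of 77 genes were measured, and the 3 past 2-fold were in the tables only through their cavefish values. Of 9521 genes, 366 were at least 2-fold higher and 969 at least 2-fold lower in the cavefish eye on the log2(RPKM + 1) scale, and 8186 lay within 2-fold. The median log2 ratio of all genes was -0.27. This shift sets the balance of those counts. With log2 ratios centred on their median, 650 genes were higher and 545 lower. Of the genes past 2-fold, 45.6% were then lower in place of 72.6%. The 2 most abundant genes held 53.2% of the RPKM total in the surface fish eye and 62.6% in the cavefish eye. Equal totals without the 50 most abundant genes of either library brought the median of all genes to -0.02. Across genes, the libraries correlated with a Pearson coefficient of 0.87 and a Spearman coefficient of 0.82; genes are not independent replicates. Each gene list below is set against 10000 random lists of genes of like abundance, which carry the same shift of all genes. Counts of list members past 2-fold are on the deposited scale and carry this shift too. Random genes need not vary together as genes of 1 tissue can. A place outside all random lists is thus a description of these 2 libraries and no measure of significance.

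**Figure D1:**
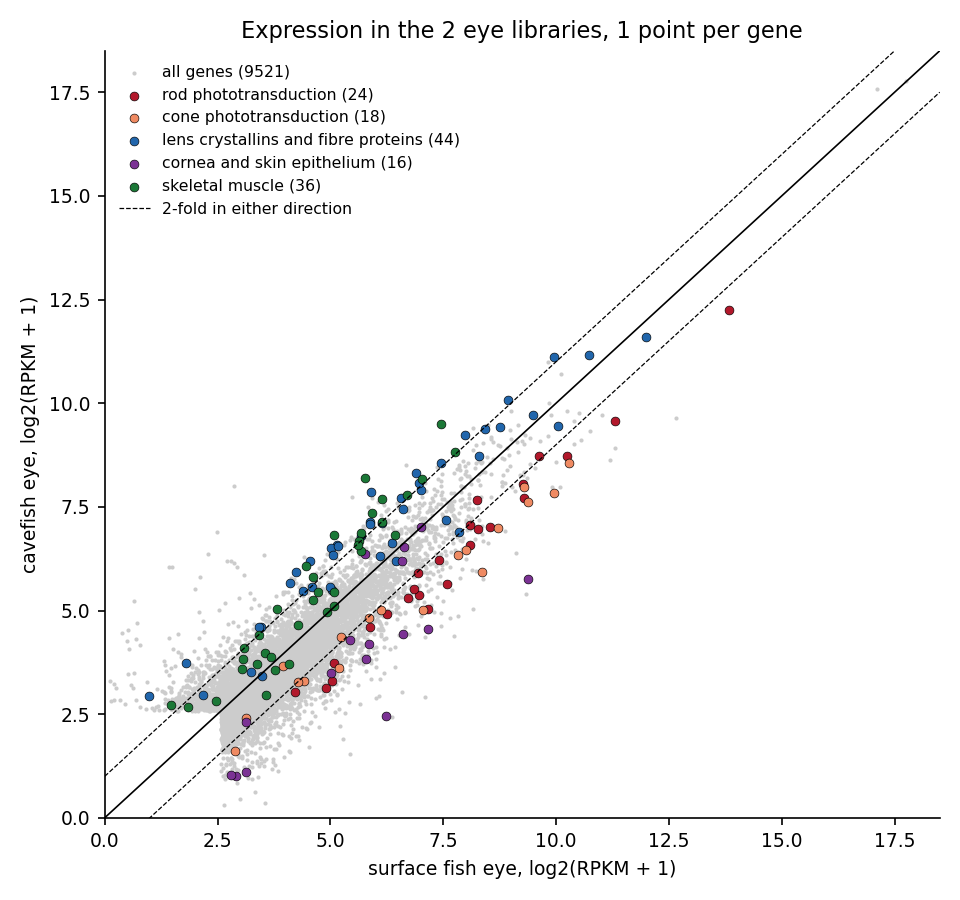
Expression of 9521 genes in the surface fish eye (x axis) and the cavefish eye (y axis), both as log2(RPKM + 1) on the deposited scale, with 1 library per species. Coloured points are members of 5 gene lists and dashed lines mark 2-fold; 22 of 24 rod phototransduction genes lie on or under the lower line, and 23 of 44 lens genes on or above the upper line.

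Photoreceptor genes were lower in the cavefish eye as a group. Of 24 measured rod phototransduction genes, 22 were at least 2-fold lower and none was higher; the list median was -1.38, below all 10000 random lists. Rhodopsin, the light-absorbing pigment of rods, was the most abundant named eye gene of both libraries, at 14606 RPKM in the surface fish and 4884 RPKM in the cavefish, a log2 ratio of -1.58. The rod transducin gene gnat1, which passes the signal from rhodopsin to the phosphodiesterase, stood at 2542 and 759.7 RPKM (-1.74). Its partner gnb1a stood at 1204 and 421.6 RPKM, and the arrestin saga, which ends the light response, at 625.9 and 207.9 RPKM. Of 18 cone phototransduction genes, 14 were at least 2-fold lower, with a median of -1.40, also below all random lists. Both counts are on the deposited scale. With log2 ratios centred on their median, the rod median was -1.10 and the cone median -1.12, still below all random lists. Members just past the threshold on the deposited scale come under 2-fold there, so fewer pass it. The long-wave cone opsin opn1lw1 stood at 984.2 RPKM in the surface fish eye and 227.6 RPKM in the cavefish eye, a log2 ratio of -2.11. The cone phosphodiesterase subunit pde6h stood at 1244 and 377.7 RPKM, the cone arrestin arr3a at 664.4 and 194.0 RPKM, the cone transducin subunit gngt2a at 627.5 and 250.0 RPKM, and the cone transducin gene gnat2 at 422.0 and 126.1 RPKM. No value for opn1sw1 was matched in the tables.

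Transcription factors of the retina had a median of -0.03 over 29 genes, above 98.6% of their random lists. The sign of this median depends on the scale, since each of the 4 other scalings moves the median of all genes up, and the median there was up to 0.24; with quantile normalization the list lay inside its random range, at percentile 91.9. Among them, 4 were at least 2-fold lower and 2 at least 2-fold higher. The lower ones were otx5, a homeobox gene of photoreceptors and pineal cells (232.2 and 102.9 RPKM), neurod1 (186.6 and 71.5 RPKM), nr2e3, a nuclear receptor needed for rod identity (107.6 and 45.6 RPKM), and the retinal homeobox gene rx2 (50.8 and 23.9 RPKM). With each of the 4 other scalings otx5, nr2e3 and rx2 came under 2-fold, at -0.74 to -0.95, and only neurod1 stayed past it. The photoreceptor regulator crx stood at 106.4 and 74.6 RPKM, a log2 ratio of -0.51, and rorb at 60.4 and 39.3 RPKM, a log2 ratio of -0.61, both within 2-fold. The eye regulators otx2b (0.22), pax6a (0.60) and pax6b (-0.18) were within 2-fold as well. The 2-fold higher ones, sox2 and lhx2b, genes of retinal progenitors and glia, stood at 11.6 and 26.1 RPKM and at 7.88 and 21.9 RPKM.

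In the visual cycle and retinal pigment epithelium list, 5 of 23 genes were at least 2-fold lower and the median of -0.60 lay at percentile 0.98. The members past 2-fold with the highest values were rbp3, which carries retinoids between photoreceptors and pigment epithelium (234.6 and 111.6 RPKM), the photoreceptor retinol dehydrogenases named retinol dehydrogenase 8 (135.8 and 66.5 RPKM) and retinol dehydrogenase 8 like (29.5 and 10.5 RPKM), and a photoreceptor retinoid transporter of the ABCA4 type (18.2 and 7.87 RPKM). With each of the 4 other scalings rbp3, retinol dehydrogenase 8 and the ABCA4-type transporter came under 2-fold, at -0.72 to -0.87. Another ABCA4-type row of the list, abca4a, was more abundant and within 2-fold, at 74.8 and 82.96 RPKM (0.15). The isomerase rpe65a, made in the pigment epithelium itself, stood at 207.6 and 176.8 RPKM, a log2 ratio of -0.23. Melanin and pigment cell genes had a median of 0.25 over 10 genes, at percentile 99.3. Only the premelanosome gene pmelb was past 2-fold, at 10.8 and 28.5 RPKM.

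Inner retinal neuron and synapse genes had a median of -0.09 over 40 genes, at percentile 96.2 of their random lists. By 2-fold, 7 genes were lower and 1 was higher. The list mixes both kinds of genes, so its lower members do not by themselves show a loss in inner retinal neurons. The calcium-binding protein gene cabp5 (281.1 and 62.2 RPKM), unc119b (260.3 and 122.2 RPKM), syntaxin 3A of ribbon synapses (86.7 and 31.8 RPKM) and the retinal complexin cplx4b (66.9 and 28.5 RPKM) were the most abundant of those past 2-fold; unc119b and cplx4b came under it with each of the 4 other scalings. Genes of Mueller glia and astroglia had a median of -0.25 over 14 genes, at percentile 54.4. By 2-fold, 2 of these genes were lower and none was higher. The lower ones were the glutamine synthase gene glulb (26.88 and 10.47 RPKM) and the carbonic anhydrase gene cahz (133.36 and 59.77 RPKM). The intermediate filament gene gfap, a glial marker, had the largest log2 ratio of the list, 0.80, at 71.2 and 124.7 RPKM.

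**Figure D2:**
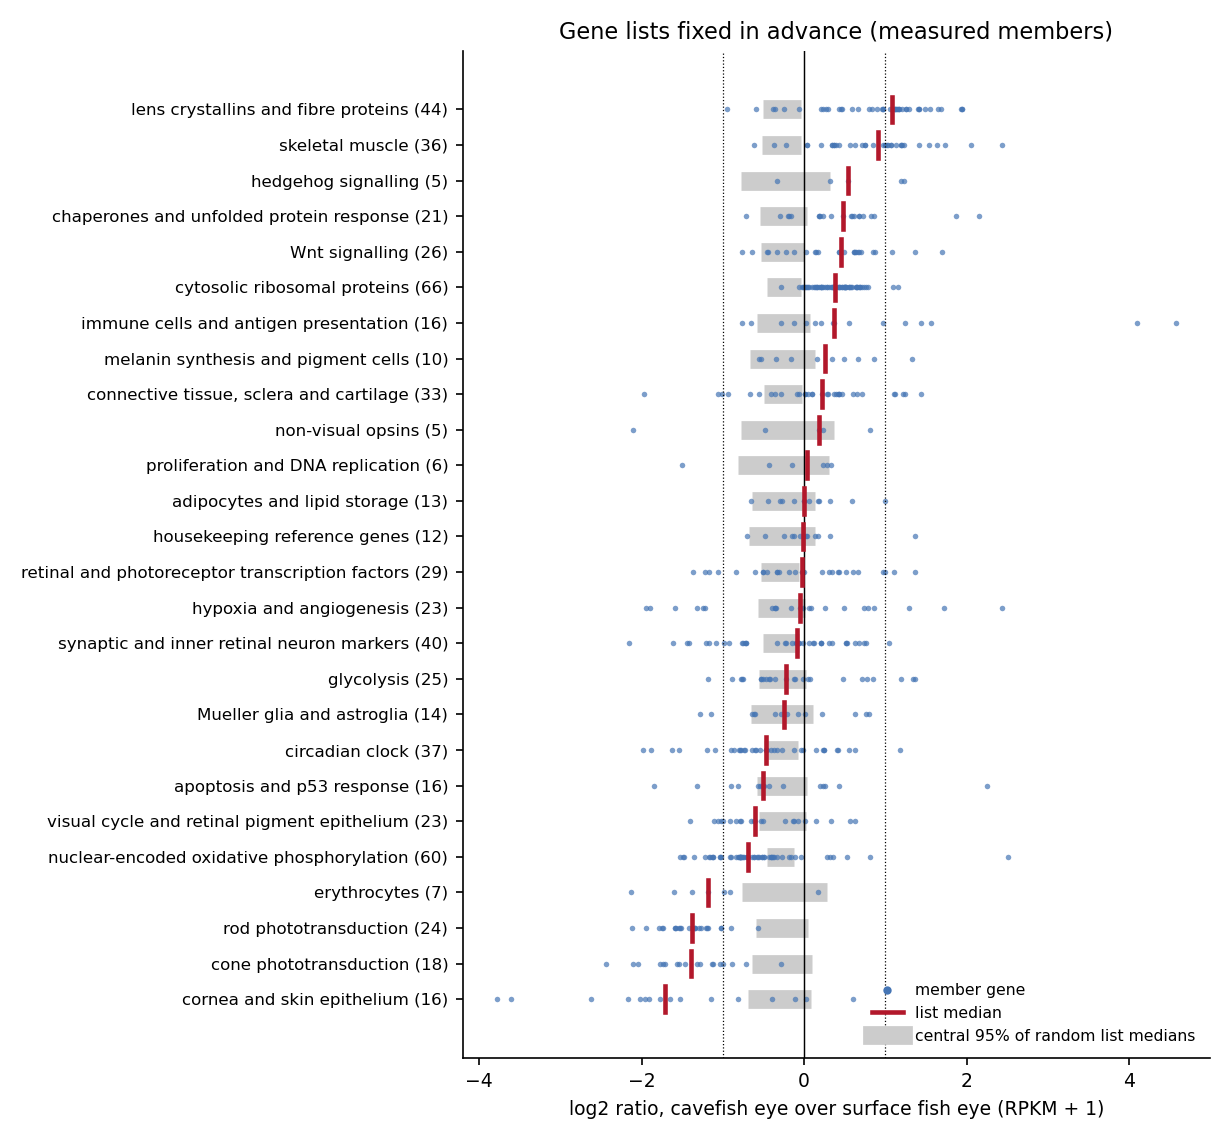
Log2 ratio of cavefish over surface fish eye, from RPKM + 1, for the measured members (points) of 26 gene lists, with the list median (red bar) and the range that holds the central 95% of medians of 10000 random lists (grey). Of the lists, 6 had a median below their grey range and 10 above it.

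Lens genes stood out in the opposite direction. Of 44 measured crystallins and lens fibre genes, 23 were at least 2-fold higher in the cavefish eye and none was 2-fold lower; the median of 1.08 lay above all 10000 random lists. Beta crystallins, structural proteins of the lens, included crystallin beta B1 like 2 (989.7 RPKM in the surface fish and 2230 RPKM in the cavefish), crybb1 (488.1 and 1085 RPKM) and crystallin beta B1 like 1 (252.8 and 604.0 RPKM). The small heat shock protein alpha B crystallin stood at 173.1 and 376.8 RPKM. The most abundant crystallin, crygs1, differed less and in the other direction, at 4046 and 3107 RPKM (-0.38), and crybb2 stood at 1696 and 2275 RPKM (0.42). Of 11 membrane, filament and other fibre genes, grouped after their values had been seen, 7 were past 2-fold, and their log2 ratios ranged from 0.27 for the filament gene bfsp2 to 1.95 for the aquaporin gene mipb. Gamma M2 crystallins are near-identical copies, and how reads were divided among them is not given in the sources used here. Many of the lens genes past 2-fold were such copies, so the count rests in part on a single copy family. No value for cryaa was matched in the tables.

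**Figure D3:**
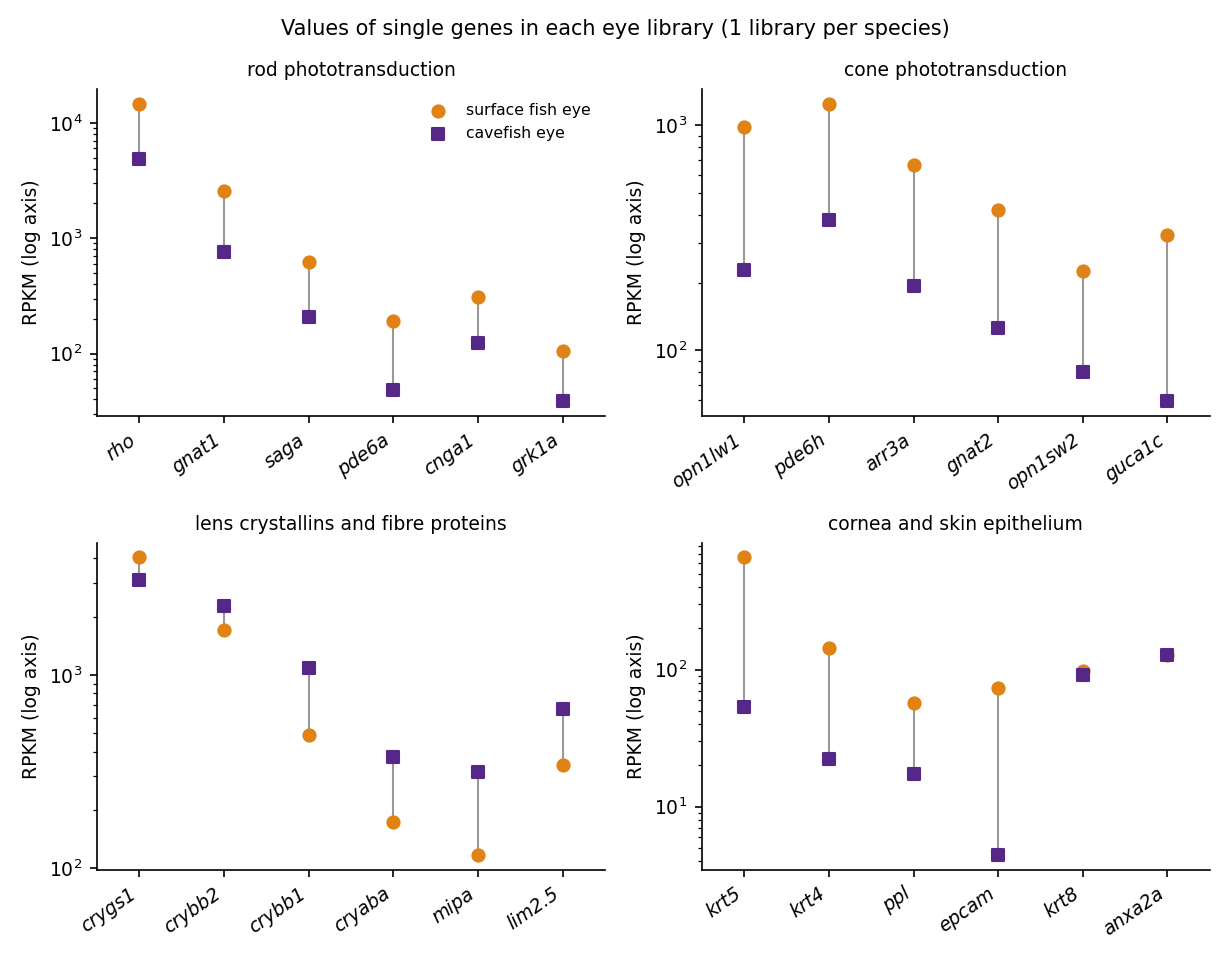
RPKM of 24 genes on log axes in the surface fish eye (circles) and the cavefish eye (squares), 1 library each, for 4 of the gene lists; grey lines join the values of a gene. Rhodopsin is lower in the cavefish eye (14606 and 4884 RPKM), crybb1 is higher (488.1 and 1085 RPKM), and krt5 is lower (660.2 and 53.3 RPKM).

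Genes of other tissues that come with a dissected eye differed as well. Cornea and skin epithelium genes had a median of -1.71 over 16 genes, below all random lists, and 11 were at least 2-fold lower; with a pseudocount of 5 the median was -1.02. Keratin 5 of basal epithelial cells stood at 660.2 and 53.3 RPKM, keratin 4 at 143.3 and 22.4 RPKM, desmoplakin, which anchors keratin filaments at cell junctions, at 96.1 and 20.6 RPKM, and epcam, an epithelial adhesion protein gene, at 74.1 and 4.46 RPKM. Keratin 8 (-0.11), keratin 18 (-0.39) and the cadherin gene cdh1 (-0.81) were within 2-fold. Skeletal muscle genes had a median of 0.91 over 36 genes, above all random lists, with 15 at least 2-fold higher and none lower. The muscle creatine kinase genes ckmb (175.2 and 727.6 RPKM) and ckma (215.1 and 453.7 RPKM), myoglobin (53.5 and 292.4 RPKM) and the myosin light chain gene mylpfa (130.6 and 285.8 RPKM) were the most abundant of these. Erythrocyte genes had a median of -1.19 over 7 genes, at percentile 0.095. Alpha globin stood at 1094 and 249.5 RPKM, the beta globin row at 540.4 and 236.6 RPKM, the red cell anion exchanger gene slc4a1a at 27.9 and 8.55 RPKM and the Rhesus glycoprotein gene rhag at 15.6 and 5.41 RPKM. The beta globin row came under 2-fold with each of the 4 other scalings, and rhag with a pseudocount of 5.

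Connective tissue, sclera and cartilage genes had a median of 0.22 over 33 genes, above all random lists, with 5 higher and 3 lower by 2-fold. The cartilage collagen col2a1a (32.4 and 77.9 RPKM), the corneal and scleral proteoglycan lumican (27.5 and 61.1 RPKM), the osteocalcin precursor of bone (26.9 and 59.2 RPKM) and col10a1 (17.9 and 50.1 RPKM) were higher. Immune and antigen presentation genes had a median of 0.36 over 16 of 59 listed genes, at percentile 99.95, with 5 higher by 2-fold. These included the class II gene mhc2dab (0.58 and 36.6 RPKM), the class I gene mhc1uba (17.4 and 53.3 RPKM), apolipoprotein c-i (3.87 and 82.0 RPKM) and complement c3a (27.6 and 66.6 RPKM); the last pair encode proteins that the liver also secretes. MHC genes are highly variable in sequence between fish, so that a low value can be a missing match. With surface fish values under 5 RPKM, mhc2dab and apolipoprotein c-i are in the tables only through the cavefish eye. Adipocyte and lipid storage genes had a median of 0.00 over 13 genes, at percentile 91.5, and none was past 2-fold.

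Nuclear genes of oxidative phosphorylation had a median of -0.70 over 60 genes, below all random lists, with 13 lower and 1 higher by 2-fold. They included cox5b of cytochrome c oxidase (125.4 and 60.8 RPKM), the ATP synthase gamma subunit gene (79.2 and 35.03 RPKM), and ndufa6 of complex I (58.0 and 22.02 RPKM). With each of the 4 other scalings cox5b and the ATP synthase gene came under 2-fold. Glycolysis genes had a median of -0.22 over 25 genes, at percentile 66.2, inside the range of their random lists; without the members shared with other lists it was -0.42 over 21 genes, at percentile 16.5, still inside. Cytosolic ribosomal protein genes had a median of 0.37 over 66 genes, above all random lists, although only rpl12 (163.6 and 349.3 RPKM) and rpl29 (97.3 and 218.5 RPKM) were past 2-fold. Chaperone and unfolded protein response genes had a median of 0.48 over 21 genes, above all random lists. The heat shock genes hsp90aa1.1 (20.3 and 76.8 RPKM) and dnajb1b (1.77 and 11.3 RPKM) were past 2-fold. With a surface fish value under 5 RPKM, dnajb1b is in the tables only through the cavefish eye. The related hsp90aa1.2 was more abundant than hsp90aa1.1 and within 2-fold, at 151.13 and 131.25 RPKM (-0.20). The hypoxia and angiogenesis list had a median of -0.05 over 23 genes, at percentile 94.35, with members on both sides: ndrg1 (961.4 and 249.3 RPKM) and epas1b (29.5 and 11.2 RPKM) were lower, and the angiogenic factor gene vegfab (9.72 and 34.3 RPKM) and myoglobin were higher. Apoptosis and p53 response genes had a median of -0.50 over 16 genes, at percentile 6.76, and proliferation genes one of 0.04 over 6 of 30 listed genes, at percentile 88.3. Housekeeping reference genes had a median of -0.01 over 12 genes, at percentile 90.9, and ranged up to 0.29 under the other scalings; beta actin stood at 919.0 and 1033 RPKM.

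Neither the clock list nor the non-visual opsin list stood apart from its random lists. Circadian clock genes had a median of -0.47 over 37 genes, at percentile 5.72, with 6 lower and 1 higher by 2-fold. The clock repressor nr1d2a (200.5 and 49.8 RPKM), the melatonin-synthesis enzyme gene aanat1 (137.2 and 63.8 RPKM), nfil3-6 (63.4 and 16.5 RPKM) and cry2 (61.0 and 26.1 RPKM) were lower; aanat1 and cry2 came under 2-fold with each of the 4 other scalings. Of the period genes, per1b (36.5 and 11.2 RPKM) and per3 (34.8 and 11.3 RPKM) were at least 2-fold lower too, and the light-inducible per2 stood at 13.1 and 7.10 RPKM, a log2 ratio of -0.80, within 2-fold. The time of day of sampling was not part of the comparison. With 1 library per species, a difference in it cannot be told apart from one of species. Non-visual opsins had a median of 0.18 over 5 of 29 listed genes, at percentile 92.1. The melanopsin row named opsin 4 stood at 34.5 and 24.5 RPKM. Of 77 listed Wnt pathway genes 26 were measured, with a median of 0.46, above all random lists. Past 2-fold were wnt2 (2.84 and 11.5 RPKM), the transcription factor gene lef1 (2.79 and 8.78 RPKM) and sfrp2 (2.07 and 5.47 RPKM). Their surface fish values lay under 5 RPKM, so these 3 genes are in the tables only through the cavefish eye. Such members can raise the median, which does not describe the pathway as a whole. Hedgehog pathway genes had a median of 0.53 over 5 of 21 listed genes, at percentile 99.6, and the co-receptor genes cdon (24.8 and 59.4 RPKM) and boc (7.65 and 18.8 RPKM) were past 2-fold. With a pseudocount of 5, lef1, sfrp2 and boc came under it.

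Among genes reaching 10 RPKM in either eye, the 12 largest ratios included secreted plasma proteins: hemopexin (1.68 and 65.8 RPKM), transferrin-a (4.63 and 118.6 RPKM) and haptoglobin (0.31 and 21.1 RPKM), which bind haem, iron and haemoglobin. The others were zgc:193613 (6.25 and 257.3 RPKM), mhc2dab, apolipoprotein c-i, alcohol dehydrogenase 8a (1.82 and 65.4 RPKM), the tyrosine-degrading enzyme 4-hydroxyphenylpyruvate dioxygenase a (0.42 and 22.1 RPKM), the lysosomal hexosaminidase A (0.64 and 24.97 RPKM), non-metastatic cells 4 (0.41 and 18.3 RPKM), uncoupling protein 1 of mitochondria (3.29 and 54.8 RPKM) and the macrophage growth factor gene colony stimulating factor 1a (0.61 and 18.8 RPKM). The error of values under 1 RPKM is not known, since depth is not. Of these genes with the largest ratios, all but zgc:193613 had surface fish values under 5 RPKM. They are thus in the tables only through the cavefish eye. The 12 smallest ratios included epithelial genes again: plakophilin 1, a desmosome protein gene (42.0 and 1.92 RPKM), epcam and keratin 5. With them stood a phosphodiesterase 5A row (95.4 and 7.22 RPKM), matrix metalloproteinase-25-like (37.8 and 2.74 RPKM), the chromatin gene jumonji, AT rich interactive domain 2a (212.0 and 20.03 RPKM), and 6 rows with only clone-based names, led by zgc:92061 (135.5 and 6.60 RPKM) and zgc:92533 (644.8 and 41.1 RPKM). Plakophilin 1, epcam, matrix metalloproteinase-25-like and some of the clone-based rows had cavefish values under 5 RPKM. Those are in the tables only through the surface fish eye.

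Most of the RPKM total of either library stood in 2 rows without a descriptive gene name. The row zgc:158463 held 32.4% of the surface fish total and 33.3% of the cavefish total, and the row Uncharacterized protein BX296557.6 held 20.8% and 29.3%. Rhodopsin followed in both, with 2.13% and 0.734%. Mitochondrially encoded cytochrome c oxidase I and cytochrome b, crygs1, gnat1, zgc:112320, cytochrome c oxidase II and pancreatic progenitor cell differentiation and proliferation factor a completed the 10 most abundant genes of the surface fish eye. In the cavefish eye these were crygs1, crybb2, crystallin beta B1 like 2, mitochondrially encoded cytochrome c oxidase III, the chaperone gene hsp90ab1 (1110 and 1659 RPKM), crybb1 and beta actin.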

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

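All alternatives were chosen before the data were examined; the number of lists standing apart, as the summary compared, and the rule by which a median counts as moved were set after the list medians had been seen. The scaling set the balance of the counts: centring on the median gave 650 genes higher and 545 lower, a trimmed mean of log2 ratios 636 and 547, equal totals without the 50 most abundant genes 603 and 555, and quantile normalization 590 and 556, against 366 and 969 on the deposited scale; these moved the median log2 ratio of all genes up by 0.25 to 0.27. By construction, a pseudocount of 5 gave fewer genes, 172 and 514, and a threshold of 4-fold 58 and 123. With a pseudocount of 0.1, 451 genes were higher and 1161 lower. The filters removed no gene and say nothing about stability. The median of the retinal transcription factors turned from -0.03 to 0.24 with centring, 0.23 with the trimmed mean, 0.22 without the most abundant genes and 0.17 with quantile normalization, since the shift of all genes was removed. The number of lists standing apart stayed at 6 below and at 9 to 11 above; the retinal transcription factors left their side with quantile normalization and with random lists from all genes, and the inner retinal neuron list reached percentile 98.4 with random lists matched on the surface fish value, with which the liver list went from percentile 99.57 to 83.0, inside its range. With quantile normalization the median of the mitochondrially encoded transcripts went from -1.11 to -0.61. Of 96 named genes past 2-fold, 74 stayed past it in the same direction under 7 alternatives, and none changed direction; of the 22 that did not stay, most came under 2-fold with the other scalings, among them otx5, nr2e3, rx2 and rbp3; rhodopsin, which ranked alike in both libraries, came to 0 with quantile normalization by construction. The median of the cornea and skin epithelium list, -1.71, was -1.02 with a pseudocount of 5, less low than those of the rod (-1.30) and cone (-1.31) lists. Without members shared with other lists the glycolysis median went from -0.22 to -0.42. The Pearson correlation fell from 0.87 to 0.85 with a pseudocount of 0.1. No paired analysis was possible because each group has 1 library. Depth is unknown, so the error of low values cannot be stated.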

Other observations

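The comparison of photoreceptor genes with all genes on the deposited scale was chosen after its value had been seen, the test on liver genes was set after the largest ratios had been seen, the choice of other lens fibre genes in the lens test was made after the values of list members had been seen, and the mitochondrial transcripts, pairs of related genes and single genes named here were singled out after their values had been seen. Transcripts of the mitochondrial genome went both ways. Of 13, 7 were at least 2-fold lower in the cavefish eye and 2 at least 2-fold higher, with a median of -1.11 at percentile 0.145; with quantile normalization the median was -0.61. Cytochrome c oxidase I stood at 6452 and 800.0 RPKM in surface fish and cavefish, cytochrome b at 2521 and 485.4 RPKM and cytochrome c oxidase II at 2078 and 834.2 RPKM, within 2-fold after quantile normalization (-0.61), while cytochrome c oxidase III stood at 898.5 and 2038 RPKM and NADH dehydrogenase 2 at 101.1 and 365.2 RPKM. Genes of 1 organelle genome and 1 respiratory complex thus differed in opposite directions.

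In several sets of related genes, 1 gene was past 2-fold while another was within it or past it the other way. Of the melatonin-synthesis genes, aanat1 had a log2 ratio of -1.09 and the row named arylalkylamine N-acetyltransferase 1.18. The complex I subunit gene ndufs8b stood at 5.39 and 35.4 RPKM and ndufs8a at 37.01 and 28.3 RPKM, within 2-fold. Gapdh, the form of general glycolysis, stood at 71.5 and 185.5 RPKM, and the row named spermatogenic form, gapdhs, at 1219 and 905.3 RPKM, within 2-fold. The melanopsin row opsin 4x1 stood at 15.9 and 2.95 RPKM, against 10.4 and 12.4 RPKM, within 2-fold, for opsin 4, like. Caspase 8, which starts death receptor signalling, stood at 2.24 and 14.4 RPKM, while the growth arrest gene gadd45ba stood at 37.4 and 9.64 RPKM.

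Photoreceptor genes were lower in the cavefish eye, with a median of -1.38 over the 42 members of the rod and cone lists. A shift of scale by a few very abundant genes moves all genes alike, whereas these members lay at -1.11 relative to the median of all genes on the deposited scale (95% interval over members -1.28 to -1.003), which argues against it as the whole cause. The test set in advance, the same difference after equal totals without the 50 most abundant genes, gave -1.10 but adds nothing, since rescaling moves the list and all genes alike. A smaller share of retina in the sample would lower all retinal cells alike. The 40 genes of the inner retinal neuron and synapse list served as the comparison. The photoreceptor median less theirs was -1.30, with an interval of -1.57 to -0.86. The list also holds synapse genes, which need not be specific to inner retinal neurons. The difference argues against a smaller share of retina as the whole cause, as far as these genes stand for other retinal cells. Intervals over members treat genes as independent and do not cover differences between animals. Fewer or smaller photoreceptors, less transcript per photoreceptor, poorer matching of cavefish reads and a difference of instrument were not tested, and the species difference that the design names stays among them.

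Lens genes were higher in the cavefish eye. If the lens made up another share of the dissected tissue, crystallins and other lens fibre genes would move alike. The crystallins had a median of 1.09 over 30 genes and the other fibre genes one of 1.13 over 11 genes, a difference of -0.039 (95% interval over members -0.91 to 0.22). The transcription factor genes hsf4, pitx3 and mafba of the list were left out of the other fibre genes, a choice made after the values of members had been seen; with them the other members had a median of 1.03 over 14 genes and the difference was 0.0534 (-0.59 to 0.47). Both intervals reach past -0.5, the bound set in advance, so that unequal shifts of that size are not excluded. The test compares 2 medians and does not see the spread within a set, where crystallins ran from -0.95 to 1.68 (crygm2a). It therefore decides neither for a larger share of lens in the cavefish sample nor for a common increase of lens transcription. Of the 30 crystallins, 25 lay above 0; the others were crygm6 (-0.95), cryba1a (-0.60), crygs1 (-0.38), crygs2 (-0.36) and crygs4 (-0.06).

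Skeletal muscle genes were higher in the cavefish eye. If more muscle was attached to the dissected eye, at least 80% of the list was predicted, before any ratio was computed, to lie past 2-fold, and under 50% if not. The share was 41.7% of 36 members (95% interval over members 25% to 58.3%). The point value thus fell on the side that speaks against more muscle, but its interval crosses the bound. The bound was also poorly chosen, which was noticed only after the result: the list median of 0.91 lies under the threshold of 1, and this alone holds the share under 50%, since a moderate common shift of muscle genes would give the same. More muscle in the sample and higher muscle gene expression therefore cannot be told apart here.

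Plasma protein genes were among the largest ratios. Liver RNA in the cavefish eye sample may bring such transcripts, and 9 other liver genes were chosen by name before their values were seen. Their median log2 ratio was 0.45 (95% interval over members -0.80 to 3.01), which does not decide, because they went both ways: 3 were at least 2-fold higher, 1 at least 2-fold lower and 5 within 2-fold. The median lay at percentile 99.57 of random lists of like abundance, but at 83.0, inside the range, of those matched on the surface fish value. The fibrinogen chains fgb (2.98 and 44.6 RPKM) and fgg (0.15 and 8.29 RPKM) and kininogen 1 (0.37 and 5.72 RPKM) were the higher ones, and betaine-homocysteine methyltransferase (19.6 and 7.62 RPKM) the lower one. The surface fish values of the 3 higher ones lay under 5 RPKM, so they are in the tables only through the cavefish eye. Liver genes low in both eyes could not enter the list. Such members can raise the median, its interval and its percentile, which do not describe liver genes as a whole. With a pseudocount of 5 both kininogen 1 and betaine-homocysteine methyltransferase came within 2-fold, the latter also with centring and the trimmed mean. The liver-type fatty acid binding protein gene fabp1a (40.7 and 22.98 RPKM) was within 2-fold. Local expression of plasma proteins in the cavefish eye was not tested, and these genes cannot be told apart from carried-over tissue, since liver was not measured.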
